A study of Mus musculus with 30 samples.

How the data were processed

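RNA was taken from the dorsal pancreas of NMRI mouse embryos at 5 stages, and labelled with biotin in 2 reactions per pool, per the labels' protocols. The labels give 30 samples, 1 per stage, chip and labelling reaction. The deposited values are log2 expression values, 1 per probe set and array, made with RMA per the submitters' processing notes, and their log base was inferred from their range. RMA corrects background, normalizes arrays by quantiles and summarises the probes of a probe set, which removes differences in overall brightness between arrays and so also any true change in total RNA per cell. Which software and version were used is not given in the sources used here. Each chip was held in a table of its own and was treated as normalized on its own, so levels were not tested between chips. Changes with stage were set across chips in the gene list tests, which took the genes of all chips together. They were also set across chips in a comparison of chips A and B in the closing section. Levels were set across chips only in choosing the probe set that represents a gene, where a higher value can come from the chip. The values come without detection calls, so a background level is unknown and dim probe sets were kept. The number of arrays limits the precision.

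Probe sets were named from GEO's platform annotation of each chip, with symbols updated through Entrez identifiers to the RefSeq annotation of GRCm38.p6, which also gave the coordinates. Of 36701 probe sets, 29131 had 1 symbol, 724 had several and 6846 were unnamed here. A gene was represented by its probe set with the highest mean log2 value over the 10 arrays of the chip; 7645 of 15964 genes had over 1 probe set. A fixed list of 28 gene groups and a set of landmark genes were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. The rule names the landmark genes, the 10 largest rises and the 10 largest falls of the stage trend that have the same sign in both reaction numbers, up to 4 members of each list with the largest passing slope (the largest slope where none passed), and the 5 largest calls in each direction of each consecutive comparison and of the middle stages against the ends. Some of the genes so named are given, and a gene from outside the rule is said to be named after its value was seen. The Wnt list entry Tcf3, meant as the older symbol of Tcf7l1, was matched to the gene now called Tcf3, which did not pass.

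Tests used limma 3.58.1 in R 4.3.3 on the log2 values. For the stage trend, the labelling reactions of a stage were averaged, and a line over embryonic day was fitted to the 5 pool means of each chip with empirical Bayes moderation. Changes are the slope times 4 days. P-values of the 3 chips were adjusted together by the Benjamini-Hochberg method, with a threshold of 0.05. For contrasts, the 10 arrays of a chip were fitted with stage as a factor, and calls needed an adjusted p under 0.05 and a change of at least 2-fold. Gene lists were tested on the slope with camera at a preset correlation of 0.01, and again with an estimated correlation. Of the 12 list calls none held with the estimated correlation, under which 1 list had an unadjusted p under 0.05.

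The functions were tested on simulated data modelled on chip A (12422 probe sets, 200 changed). The labelling SD was 0.0878, and the SD between pools was set to the median residual of the line fits, 0.0873. That residual also holds labelling noise and curvature, since 1 pool per stage gives no spread between pools. Each probe set had the same SDs, drawn independently, so false calls from shifts shared by many genes were not covered. The simulated changes ran in a straight line over embryonic day, the shape that the stage trend fits. For the stage trend 80% of such 1.5-fold changes and 100% of such 2-fold changes were recovered, with 11 false calls among 12222 unchanged probe sets. With no change simulated 1 probe set was called. Recovery of changes that come in a step was not tested, and the stage trend can miss them. The zymogen granule gene Zg16 went from 5.02 at e12.5 to 9.39 at e16.5. Its slope did not pass in the stage trend (3.69 ± 1.18, limma adjusted p = 0.0644). For e16.5 against e12.5, 44% of 2-fold and 100% of 4-fold changes were recovered. With no stage change but a spread between pools, that comparison called 0 probe sets with the 2-fold minimum and 1320 at an adjusted p under 0.05 alone. Alternatives were other scalings (quantile normalization again, median centring), a filter to bright probe sets, an intensity trend in the prior variance, adjustment within each chip, other treatments of the labelling reactions, other fold minimums, leaving out each array and each pool, and the replicate number as a block. Cyclic loess was added after the data were seen. No samples were left out.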

Results

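Gene expression was measured in the dorsal pancreas of NMRI mouse embryos at 5 daily stages from embryonic day 12.5 (e12.5) to e16.5, the days over which the pancreatic bud grows and forms its acinar, ductal and endocrine cells. Dorsal pancreata were pooled by litter, and how many litters or embryos stand behind a stage is not given in the sources used here. RNA from each pool was labelled in 2 separate reactions, and each labelled sample was hybridised to the 3 Affymetrix MG-U74 version 2 chips A, B and C. This gave 30 arrays, with 10 arrays per chip and 2 per stage and chip. Chip A held 12422 probe sets, chip B 12411 and chip C 11868. Array medians lay between 5.71 and 5.76 on chip A, between 5.26 and 5.31 on chip B and between 3.99 and 4.02 on chip C, in log2 units. Both reactions of a pool correlated at 0.996 to 0.998 over the probe sets of a chip, and no probe set differed between them by 2-fold. Both arrays of a stage share a pool, so the spread between them is technical, and a difference between stages cannot be told apart from a difference between pools. Since RNA came from dorsal pancreata and not from sorted cells, changes within cells cannot be told apart from changes in the mix of cells.

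The first comparison asked which transcripts rose or fell steadily from e12.5 to e16.5. Of the 10 largest rises, 9 were in members of the fixed lists of acinar enzymes, other acinar products and folding genes, and 1 was in an islet hormone gene. Cela3b, a pancreatic elastase, rose by 8.19 ± 0.87 (fitted log2 change over 4 days ± SE, n = 5 pools; adjusted p = 0.000892), from 5.12 ± 0.21 to 12.87 ± 0.02 (mean log2 value ± SD of 2 labelling reactions). The ribonuclease gene Rnase1 rose by 7.76 ± 1.47, and Ins2, which encodes insulin, by 7.53 ± 0.86. Carboxypeptidase B1 (Cpb1) rose by 7.44 ± 0.87 on the brighter of its 2 probe sets and not on the other, the pancreatic serpin gene Serpini2 by 7.09 ± 0.35 and the trypsinogen gene Prss2 by 6.47 ± 0.57. The lipase-related gene Pnliprp1 (6.12 ± 0.61), the disulfide isomerase gene Pdia2 (5.83 ± 0.94), the carboxyl ester lipase gene Cel (5.81 ± 0.16) and the colipase gene Clps (5.49 ± 0.34) completed the group. At e12.5, Rnase1 (2.96 ± 0.02), Serpini2 (3.65 ± 0.06), Cpb1 (4.51 ± 0.10), Pdia2 (4.99 ± 0.04), Prss2 (5.02 ± 0.02), Cela3b and Ins2 (5.28 ± 0.03) lay below the median of their chip. Without detection calls these levels are not shown to be above background, so their changes can be understated, have no order among them and are not given as folds from e12.5. On GRCm38.p6 these genes lie at chromosome 4, 137421008 to 137430520 for Cela3b, chromosome 14, 51145002 to 51146767 for Rnase1, chromosome 7, 142678656 to 142679726 for Ins2 and chromosome 3, 20249479 to 20275733 for Cpb1.

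Of the 10 largest falls, the first 2 were in globin genes of primitive red cells, Hbb-y and Hba-x, which fell by 5.52 ± 0.68 and 5.35 ± 0.42 on the log2 scale. The chromatin protein gene Hmga2 fell by 3.35 ± 0.19, or 10.2-fold. Amot, which encodes angiomotin, fell by 3.18 ± 0.27, and the matrix protein gene Tgfbi fell by 3.15 ± 0.53. Slitrk5 had a change of -2.83 ± 0.25, the imprinted gene Grb10 of -2.77 ± 0.62, with falls on 2 of its 4 probe sets, and Hand2, a transcription factor gene of mesenchyme and neural crest, of -2.72 ± 0.12. Rdh10, an enzyme of retinoic acid synthesis, changed by -2.65 ± 0.18 and the integrin gene Itga8 by -2.58 ± 0.54. Hmga2 lies at chromosome 10, 120361268 to 120476469 and Hand2 at chromosome 8, 57320983 to 57324517 on GRCm38.p6. Adjusted p-values of these 20 genes ran up to 0.0226, that of Grb10. Without the e16.5 pool the changes of Rnase1, 5.53 (adjusted p = 0.114), and Grb10, -1.55 (adjusted p = 0.167), no longer passed. Neither did Grb10 without the e13.5 pool, at -2.56 (adjusted p = 0.0607), nor Itga8 without the e12.5 pool, at -1.83 (adjusted p = 0.106).

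In all, 3886 of 36701 probe sets rose and 4825 fell (limma slope over the 5 pool means, Benjamini-Hochberg adjusted p under 0.05). By 1 probe set per gene, these were 1902 rising and 2709 falling genes of 15964. A change of at least 2-fold as well was reached by 525 rising and 981 falling probe sets. The rising count was 1275 without the e16.5 pool, 1874 without the e12.5 pool and 2207 without the e13.5 pool, and the falling count was 2278 without the e16.5 pool. Of 124 genes under the naming rule with a passing slope, 67 had over 1 probe set. In 3 of these, C1qb, Jag1 and Tug1, another probe set passed the other way. In 19 a probe set above the median of its chip did not pass, among them Rdh10, Grb10, Pdgfra, Sox4, Sox9, Isl1, Yap1, Vwf, Cd34, Fgfr2, Agrn, Fosl2, C1qc, Kctd14, Sfpq and Rpl22. In 24 another passed the same way with a change over 1.5-fold apart, such as those of Hand2 (-1.46 ± 0.11), Slc38a4 (-2.35 ± 0.15), Fkbp11 (3.34 ± 0.39) and Cela2a (2.93 ± 0.88). Of 59 rising genes under the rule, 22 lay below the median of their chip at e12.5, among them Amy2a5, Ero1b, Klk1, Sycn, Scg2, Sytl4, Vil1, Alb, Aldh1a1 and Itga6. Of 65 falling ones 11 lay below it at e16.5, among them Amot, Mycn, Gdf11, Isl1, Lama1, Wnt5a, Wt1, C1qb and Sfpq. Changes of these genes can be understated. Alb, which rose, and Vim, Onecut1, Neurod1 and Pax6, which had no passing slope, lay below the median of their chip at each stage. What these genes did is thus not shown by levels above background.

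**Figure D1:**
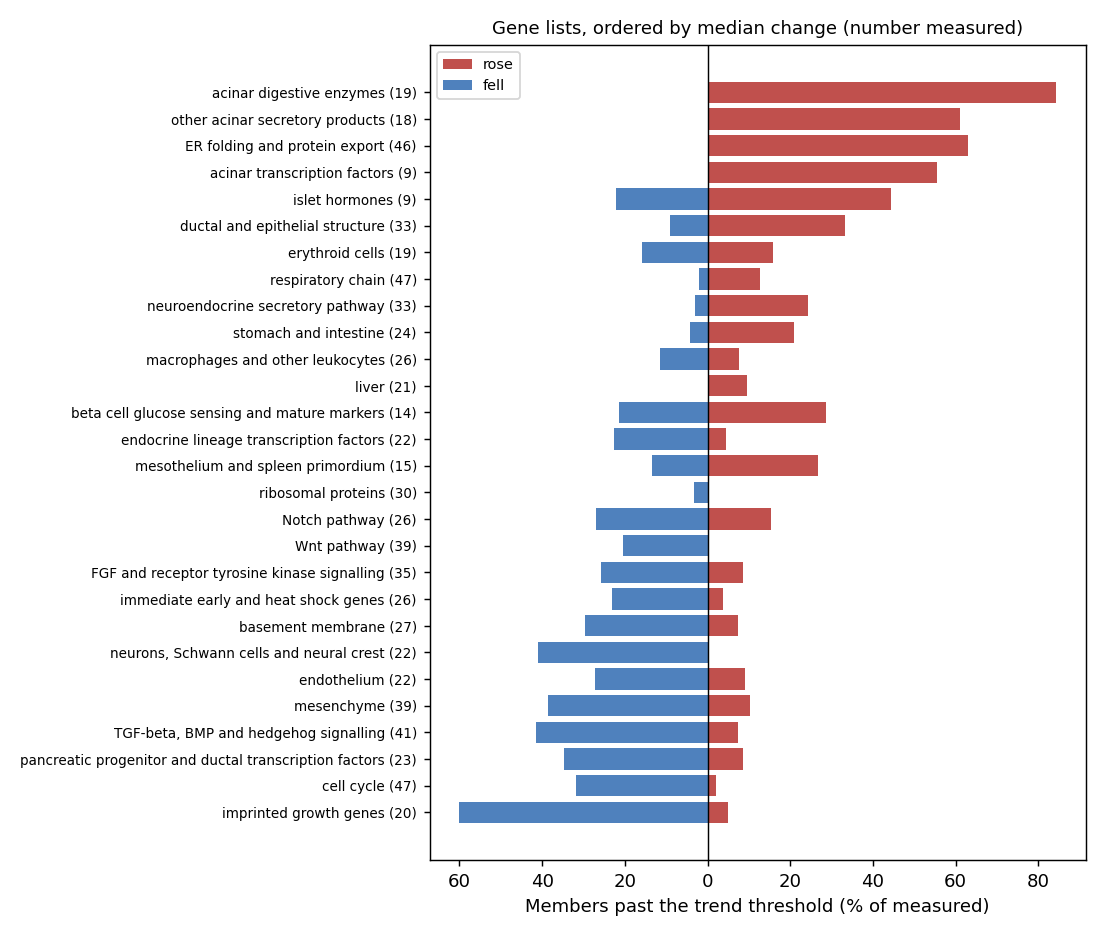
Share of measured members of each gene list that rose (right) or fell (left) with stage, in percent, with the number measured in brackets and lists ordered by median change. Of the 19 acinar digestive enzymes 16 rose, and of the 20 imprinted growth genes 12 fell.

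Of 19 genes of the digestive enzymes that acinar cells make and secrete, 16 rose, none fell and 3 did not pass (19 rising and 0 falling adjusted over the list alone), with a median change of 5.04. Besides the genes above, Cela1 rose by 5.05 ± 0.16, Cela2a by 5.19 ± 0.79, the chymotrypsinogen gene Ctrb1 by 5.44 ± 0.81, the amylase gene Amy2a5 by 3.87 ± 0.65 and the carboxypeptidase gene Cpa1 by 2.58 ± 0.31. Ctrb1 was the brightest probe set of chip A at e15.5 and e16.5 (14.08 ± 0.04 and 14.20 ± 0.04), and Cpa1 that of chip C from e14.5 on (13.31 ± 0.02 at e16.5). Signal can saturate there, so both changes can be understated. Cela3b was the brightest probe set of chip B at e16.5. Clps (13.84), Cel (13.23) and Pnliprp1 (12.86) at e16.5 and Hbb-y (13.15) at e12.5 were also near the top of chip A. Changes of these genes can be understated for the same reason. Amy2a5 started at 3.31 ± 0.52, below the median of its chip. The camera test gave an adjusted p of 2.94e-11 for this list against the other genes, and an adjusted p = 0.496 with an estimated correlation between genes. Other acinar secretory products had 11 rising members of 18 and none falling (15 rising and 0 falling adjusted over the list alone; adjusted p = 1.14e-07, and adjusted p = 0.496 with an estimated correlation). Among them the zymogen granule gene Sycn rose by 5.38 ± 1.19, Fkbp11 by 5.06 ± 0.52 and the cholecystokinin receptor gene Cckar by 3.99 ± 0.25. Sycn did not pass without the e16.5 pool, at 2.52 (adjusted p = 0.0611), or without the e13.5 pool, at 5.27 (adjusted p = 0.0579). Of 9 acinar transcription factor genes, 5 rose and none fell (6 rising and 0 falling adjusted over the list alone; adjusted p = 0.00236, and adjusted p = 0.496 with an estimated correlation). Bhlha15 (Mist1) rose by 3.43 ± 0.23, Ptf1a by 2.18 ± 0.19 (and by 3.45 ± 0.28 on a second probe set), Xbp1 by 1.40 ± 0.11 and Nr5a2 by 0.82 ± 0.17, the last with a change of 0.50 (adjusted p = 0.106) without the e12.5 pool. Of 46 genes of folding and export in the endoplasmic reticulum, 29 rose and none fell (31 rising and 0 falling adjusted over the list alone; adjusted p = 2.94e-11, and adjusted p = 0.496 with an estimated correlation), among them Ero1b (4.27 ± 0.33), Herpud1 (2.78 ± 0.38) and Dnajc3 (2.58 ± 0.34). The probe sets used for Ins2, Prss2, Pdia2, Klk1, Ero1b, Ppy, Chgb, Foxa3, Hbb-y, Grb10, Gap43, Alas2, Ednrb and Sfpq are of a design shared by similar sequences, so their values can hold signal from related genes such as other trypsinogens or Ins1. Those of Ctrb1, Serpini2, Amy2a5, Gcg, Dnajc3, Egfl6, Eif5a2 and Prdm16 were made under relaxed probe rules or with an incomplete probe set.

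**Figure D2:**
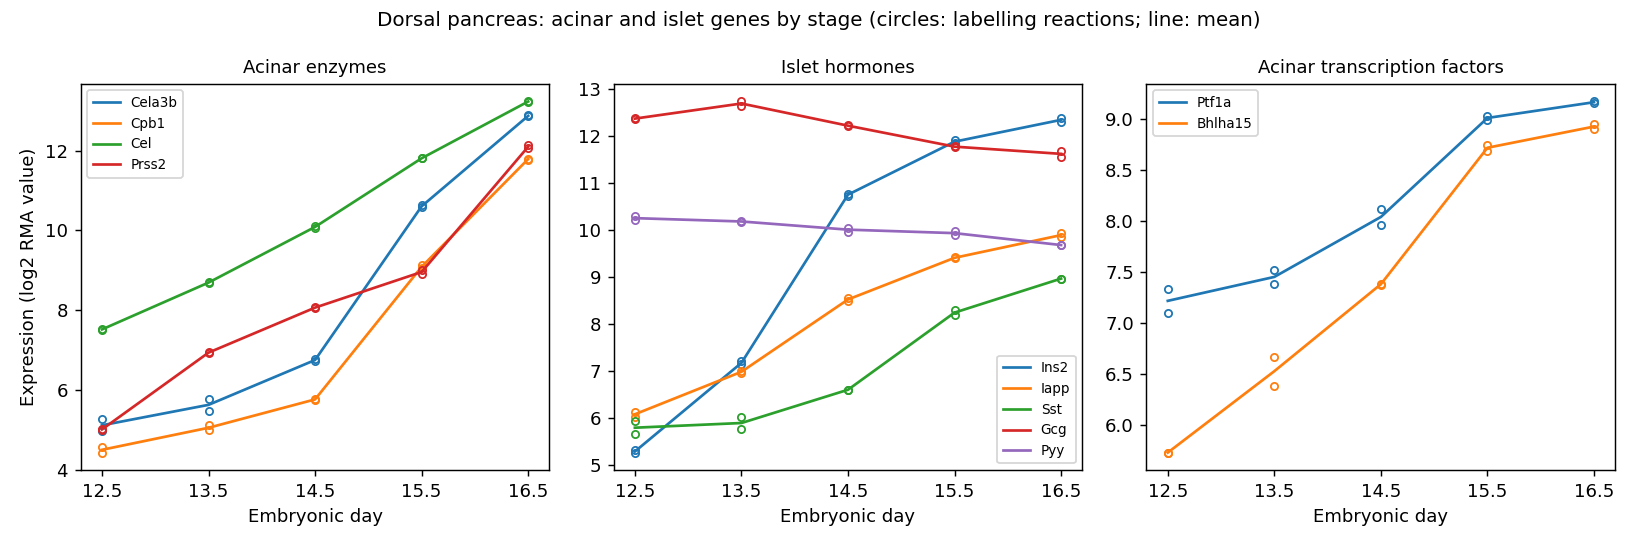
Log2 expression (y axis) of acinar enzyme, islet hormone and acinar transcription factor genes by embryonic day (x axis), with a circle per labelling reaction and a line through the mean of the 2. Cela3b went from 5.12 to 12.87, Ins2 rose and Gcg fell.

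Of 9 islet hormone genes, 4 rose, 2 fell and 3 did not pass (5 rising and 2 falling adjusted over the list alone), and the list did not pass as a whole (adjusted p = 0.159), though it passed upward without the e16.5 pool (adjusted p = 0.0179). Ins2 rose by 7.53 ± 0.86 on its probe set with the higher mean and by 0.85 ± 0.18 on the other, which went from 6.71 to 7.48. The islet amyloid gene Iapp rose by 4.02 ± 0.28, the somatostatin gene Sst by 3.48 ± 0.40 and the pancreatic polypeptide gene Ppy by 0.54 ± 0.10. Gcg, which encodes glucagon, was already at 12.37 ± 0.01 at e12.5, as the brightest probe set of chip C, where signal can saturate, and fell by 0.97 ± 0.20, with a fall of 1.53 ± 0.38 on its probe set on chip A, while the peptide YY gene Pyy, named after its value was seen, fell by 0.56 ± 0.10. Without the e16.5 pool Gcg had a change of -0.90 (adjusted p = 0.0975) and Ppy one of 0.55 (adjusted p = 0.0627). Of 33 genes of the neuroendocrine secretory pathway, 8 rose and 1 fell (8 rising and 2 falling adjusted over the list alone; adjusted p = 0.00682, and adjusted p = 0.496 with an estimated correlation). The risers included the granule transport gene Rab3d (3.50 ± 0.26), which acinar cells also use, Rab27a (1.97 ± 0.14), the secretogranin gene Scg2 (1.90 ± 0.13) and Sytl4 (1.25 ± 0.13). This list did not pass without the e12.5 pool (adjusted p = 0.165). The chromogranin gene Chga had a change of 0.63 ± 0.24 (adjusted p = 0.102), and its second probe set passed, at 0.51 ± 0.12; without the e16.5 pool the first gave 1.10 (adjusted p = 0.0374). In the list of beta cell genes, 4 of 14 rose and 3 fell (4 rising and 5 falling adjusted over the list alone; adjusted p = 0.58), with Npy at 1.49 ± 0.24 and Cltrn at -1.36 ± 0.15.

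Of 22 transcription factor genes of the endocrine lineage, 1 rose and 5 fell (2 rising and 5 falling adjusted over the list alone; adjusted p = 0.411). The falls were in Sox11 (-2.50 ± 0.23), Sox4 (-1.55 ± 0.19), Rfx3 (-1.33 ± 0.14), Runx1t1 (-1.13 ± 0.14) and Isl1 (-0.94 ± 0.15), and Isl1 gave -0.77 (adjusted p = 0.056) without the e16.5 pool. The list's median was 0.02, its mean was -0.30 and its test pointed down, and it passed without the e12.5 pool (adjusted p = 0.00266). Neurog3, the factor that starts the endocrine program, had no slope past the threshold (0.33 ± 0.52), nor had Neurod1 (0.02 ± 0.35), Pax4 (0.02 ± 0.20), Pax6 (-0.10 ± 0.28) or Nkx2-2 (-1.01 ± 0.53). Without the e12.5 pool, Neurog3 (-1.04, adjusted p = 0.0284) and Nkx2-2 (-2.16, adjusted p = 0.0215) fell, so that the slope of Neurog3 changed sign. Genes of the progenitor and ductal factors numbered 2 rising and 8 falling of 23 (3 rising and 9 falling adjusted over the list alone; adjusted p = 0.107, and 0.00806 without the e12.5 pool and 0.0314 with the mean of all probe sets of a gene). Mycn fell by 1.82 ± 0.22, Id3 by 1.46 ± 0.15, Yap1 by 1.06 ± 0.14 and Sox9, a progenitor and duct factor, by 0.74 ± 0.16, while Foxa3 rose by 1.21 ± 0.12. Sox9 gave -0.39 (adjusted p = 0.176) without the e16.5 pool. Pdx1 (-0.05 ± 0.31) and Onecut1 (-0.36 ± 0.18) did not pass, and Onecut1 fell without the e12.5 pool (-0.73, adjusted p = 0.036). Nkx6-1, Ins1, Pcsk2 and Spp1 were among the landmark genes not analysed here.

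Of 33 genes of ductal and epithelial structure, 11 rose, 3 fell and 19 did not pass (11 rising and 3 falling adjusted over the list alone; adjusted p = 0.00167, and adjusted p = 0.496 with an estimated correlation). Clu rose by 3.68 ± 0.19, the mucin gene Muc1 by 2.72 ± 0.14, and the keratin genes Krt18 and Krt19 by 2.08 ± 0.09 and 1.49 ± 0.17. Among 39 mesenchyme genes, 15 fell, 4 rose and 20 did not pass (7 rising and 16 falling adjusted over the list alone; adjusted p = 0.0414, and adjusted p = 0.506 with an estimated correlation). Besides Hand2, the transcription factor genes Tcf21 (-2.57 ± 0.22) and Snai2 (-1.99 ± 0.19) and the receptor gene Pdgfra (-1.67 ± 0.22) fell, whereas Dcn, which encodes decorin, rose by 1.29 ± 0.19. Col1a1 (-0.29 ± 0.20) and Vim (0.28 ± 0.09) did not pass, although Vim did with arrays centred on their median (adjusted p = 0.0412) and without e16.5 replicate 1 (adjusted p = 0.0428). The mesenchyme call was lost without e12.5 replicate 2 (adjusted p = 0.0623), without e16.5 replicate 1 (0.0609), in e16.5 against e12.5 over 10 arrays (0.0618), with cyclic loess (adjusted p = 0.0882), with bright probe sets only (0.138), without the e12.5 pool (0.0542), without the e14.5 pool (0.0647) and without the e15.5 pool (0.0613). Basement membrane genes gave 2 rises and 8 falls among 27 (3 rising and 10 falling adjusted over the list alone; adjusted p = 0.293), with Lama1 at -1.64 ± 0.14, Agrn at -1.13 ± 0.22 and Itga6 at 1.94 ± 0.34. Agrn gave -0.75 (adjusted p = 0.098) without the e16.5 pool and Itga6 1.45 (adjusted p = 0.0641) without the e12.5 pool.

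Markers of other cell types in or near the bud were followed in the same way. Neural and Schwann cell genes had 9 falling members of 22 and none rising (1 rising and 9 falling adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.496 with an estimated correlation), among them Gap43 (-2.04 ± 0.16), Nefm (-1.81 ± 0.23), Ednrb (-1.75 ± 0.26) and Ncam1 (-1.72 ± 0.16). Endothelial genes gave 2 rises and 6 falls of 22 (3 rising and 7 falling adjusted over the list alone; adjusted p = 0.112), with Vwf at -1.22 ± 0.20 and Cd34 at 0.58 ± 0.09, and Pecam1 (-0.08 ± 0.10) did not pass. This list passed downward without the e16.5 pool (adjusted p = 0.0179), and Vwf then gave -1.28 (adjusted p = 0.0506). Of 19 red cell genes 3 rose and 3 fell (4 rising and 3 falling adjusted over the list alone; adjusted p = 0.363). The embryonic globin genes Hbb-y, Hba-x and Hbb-bh1 (-1.35 ± 0.21) fell, and Alas2, an enzyme of haem synthesis, rose by 1.77 ± 0.29; Alas2 gave 1.77 (adjusted p = 0.0588) without the e16.5 pool. The list's median was 0.17, its mean was -0.36 and its test pointed up, passing without the e12.5 pool (adjusted p = 0.0435) and pointing down without the e16.5 pool (adjusted p = 0.874). Leukocyte genes had 2 rises and 3 falls of 26 (2 rising and 3 falling adjusted over the list alone; adjusted p = 0.419). The list passed upward without the e12.5 pool (adjusted p = 0.0479) and downward without the e16.5 pool (adjusted p = 0.0185). Its members S100a8 and S100a9, genes of neutrophils named after their values were seen, were higher at e16.5 than at e15.5 by 2.84 ± 0.06 and 2.78 ± 0.09. The complement genes C1qa (1.72 ± 0.44), C1qb (-0.92 ± 0.23) and C1qc (-0.50 ± 0.14) moved in different directions, and a second probe set of C1qb rose by 1.60 ± 0.45. C1qc did not pass with quantile normalization again (adjusted p = 0.0869), with arrays centred on their median (0.0513), with cyclic loess (0.148), without e14.5 replicate 1 (0.0535), without e16.5 replicate 1 (0.06), or without the e12.5, e13.5 or e15.5 pool (0.239, 0.109 and 0.0847). C1qa gave 0.875 (adjusted p = 0.27) without the e16.5 pool, 1.65 (0.0864) without the e13.5 pool and 1.78 (0.0679) without the e15.5 pool. C1qb gave -0.55 (adjusted p = 0.215) without the e12.5 pool, -0.94 (0.0732) without the e13.5 pool and -0.81 (0.0644) without the e15.5 pool. Genes of mesothelium and spleen primordium had 4 rises and 2 falls of 15 (4 rising and 2 falling adjusted over the list alone; adjusted p = 0.538), with Aldh1a1 at 3.71 ± 0.32 and Wt1 at -1.14 ± 0.13. Liver genes had 2 rises of 21 and no fall (2 rising and 0 falling adjusted over the list alone; adjusted p = 0.561), with Alb at 1.11 ± 0.21. Stomach and intestine genes had 5 rises and 1 fall of 24 (5 rising and 1 falling adjusted over the list alone; adjusted p = 0.0575, and 0.0407 with arrays centred on their median), with Vil1 at 2.41 ± 0.31. This list also passed without e15.5 replicate 1 (adjusted p = 0.0466), without e16.5 replicate 1 (0.0486), without the e12.5 pool (0.0386), without the e15.5 pool (0.0428) and in e16.5 against e12.5 over 10 arrays (0.041).

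Of 47 cell cycle genes, 15 fell, 1 rose and 31 did not pass (2 rising and 23 falling adjusted over the list alone; adjusted p = 8.61e-06, and adjusted p = 0.589 with an estimated correlation), and the list did not pass without the e16.5 pool (adjusted p = 0.0863). Stmn1 fell by 1.49 ± 0.20, the replication genes Mcm4 and Pcna by 1.29 ± 0.28 and 1.18 ± 0.25, and the kinetochore gene Cenpf by 1.18 ± 0.15. Without the e13.5 pool Mcm4 (-1.29, adjusted p = 0.0556) and Pcna (-1.15, adjusted p = 0.0557) did not pass. The median difference over the 47 genes was -0.09 from e12.5 to e13.5, 0.02 and -0.03 over the next intervals and -0.63 from e15.5 to e16.5, where 3 genes were at least 2-fold lower. The intervals were not tested against each other. Imprinted growth genes had 12 falls and 1 rise, that of Dcn, of 20 (1 rising and 16 falling adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.496 with an estimated correlation), with Peg3 at -1.39 ± 0.19 and Slc38a4 at -1.29 ± 0.17. TGF-beta, BMP and hedgehog genes had 17 falls and 3 rises of 41 (5 rising and 19 falling adjusted over the list alone; adjusted p = 0.00288, and adjusted p = 0.496 with an estimated correlation), with Tgfbr1 at -1.79 ± 0.15, Gdf11 at -1.61 ± 0.12 and Id3 as above. Wnt pathway genes had 8 falls of 39 and no rise (0 rising and 8 falling adjusted over the list alone; adjusted p = 0.0854, and 0.0154 with the mean of all probe sets of a gene), with Sfrp1 at -2.39 ± 0.28, Wnt5a at -1.97 ± 0.22 and Fzd2 at -1.43 ± 0.17. FGF and receptor kinase genes had 9 falls and 3 rises of 35 (4 rising and 9 falling adjusted over the list alone; adjusted p = 0.159, and 0.0425 with bright probe sets only), with Fgfr2 at -1.49 ± 0.26 and Spry1 at -1.03 ± 0.14; Fgfr2 gave -1.11 (adjusted p = 0.085) without the e16.5 pool. Notch pathway genes had 7 falls and 4 rises of 26 (4 rising and 8 falling adjusted over the list alone; adjusted p = 0.38). Jag1 fell by 0.73 ± 0.11 on its brightest probe set and by 1.67 ± 0.11 on the other of chip B, while of its 2 probe sets on chip C 1 did not pass and 1 rose by 0.33 ± 0.08. Respiratory chain genes had 6 rises and 1 fall of 47 (1 rising and 1 falling adjusted over the list alone; adjusted p = 0.00236, and adjusted p = 0.589 with an estimated correlation), with Ndufb9 at 0.94 ± 0.18, or 0.71 (adjusted p = 0.104) without the e16.5 pool. Ribosomal protein genes had 1 fall of 30, that of Rpl22, and no rise (0 rising and 1 falling adjusted over the list alone; adjusted p = 0.626). Immediate early and heat shock genes, which respond to handling, had 6 falls and 1 rise of 26 (2 rising and 6 falling adjusted over the list alone; adjusted p = 0.159, and 0.0306 without the e12.5 pool), with Hsph1 at -1.62 ± 0.24 and Fosl2 at -1.08 ± 0.10.

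The second comparison set the last pool against the first. Ins2 went from 5.28 ± 0.03 at e12.5, a level not shown above background, to 12.34 ± 0.07 at e16.5. Iapp was 14.1-fold higher at e16.5 than at e12.5, with a log2 difference of 3.81 ± 0.06 (SE over labelling reactions, 10 arrays), Sst 9.03-fold, Cela1 30.3-fold and Ptf1a 3.85-fold higher, with 8.64-fold for a second probe set of Ptf1a. Ctrb1 read 43.8-fold higher, at the top of the range of chip A, where saturation can hold the value down. Gcg had a log2 difference of -0.75 ± 0.07 on the chip C probe set, bright enough at e12.5 to saturate, and of -1.16 ± 0.10 on that of chip A. Sox9 had one of -0.76 ± 0.08, short of 2-fold. Of 19 digestive enzyme genes, 18 were at least 2-fold higher, and of 47 cell cycle genes 15 were at least 2-fold lower. Across the chips, 527 probe sets were higher and 1111 lower (limma, adjusted p under 0.05 and at least 2-fold). The error of this test holds the spread between labelling reactions only, so it compares pools and not stages. The same goes for the consecutive comparisons and for the middle stages against the ends. Without a fold minimum e16.5 against e12.5 gave 9687 probe sets higher and 8594 lower.

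Consecutive pools were then compared, to place the changes in time. From e12.5 to e13.5, Ctrb1 rose 6.18-fold, Pnliprp1 4.14-fold and the chromogranin B gene Chgb 3.72-fold. From e12.5 levels not shown above background, Serpini2 rose to 5.92 ± 0.04 and Prss2 to 6.94 ± 0.02. Xist, the noncoding RNA expressed from the inactive X chromosome, changed by -1.61 ± 0.07 on the log2 scale, in pools whose mix of sexes is not given in the sources used here. Further changes were those of Sfrp1, by -1.16 ± 0.08, AW551984 by -1.13 ± 0.07, Eif5a2 by -1.12 ± 0.10 and Hba-x by -1.08 ± 0.07. Sfrp1 fell short of 2-fold with quantile normalization again (-0.99), and Eif5a2 did so without e12.5 replicate 1 (-0.99) and without e13.5 replicate 2 (-0.96). From e13.5 to e14.5 the largest step was that of Ins2, 12-fold, with Pnliprp1 at 5.01-fold and Iapp at 2.91-fold, while Tgfbi (-1.72 ± 0.07), Itga8 (-1.59 ± 0.08), Slitrk5 (-1.11 ± 0.07) and Rdh10 (-1.04 ± 0.07) fell, Rdh10 by under 2-fold without e13.5 replicate 1 (-0.98). From e14.5 to e15.5 Cela3b rose 14.4-fold, Cpb1 9.99-fold, Cela2a 6.61-fold and Kctd14 6.56-fold. Rnase1 went from 3.09 ± 0.04 to 7.57 ± 0.04, and since the first is not shown above background no fold is given. Hbb-y (-1.87 ± 0.06), Hba-x (-1.71 ± 0.07), Prdm16 (-1.46 ± 0.26), Tug1 (-1.36 ± 0.09) and Amot (-1.31 ± 0.09) fell, and over the 5 pools 3 of the 4 probe sets of Tug1 fell and 1 rose. From e15.5 to e16.5 the zymogen granule gene Sycn (13.3-fold), the kallikrein gene Klk1 (9.15-fold), Prss2 (8.8-fold) and Pdia2 (8.05-fold) rose, and Hbb-y (-2.52 ± 0.06), Hba-x, Egfl6 (-1.57 ± 0.08), Grb10 (-1.51 ± 0.06) and Sfpq (-1.39 ± 0.09) fell. Eif5a2 at e13.5 and Sfpq at e16.5 lay below the median of their chip, so these falls can be understated. The zymogen granule gene Zg16 rose from 5.53 ± 0.12, below the chip median, to 9.39 ± 0.05, and had no slope past the threshold over the 5 pools (3.69 ± 1.18, adjusted p = 0.0644). In these 4 intervals 29, 39, 108 and 79 probe sets were at least 2-fold higher and 18, 9, 26 and 42 at least 2-fold lower. With no fold minimum lower calls outnumbered higher ones in each interval, with 2053 higher and 2069 lower, 494 and 666, 1814 and 2108, and 3050 and 4488. At 1.5-fold the numbers were 108 and 193, 106 and 90, 336 and 241, and 244 and 617, so that lower calls led in the first and the last interval.

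**Figure D3:**
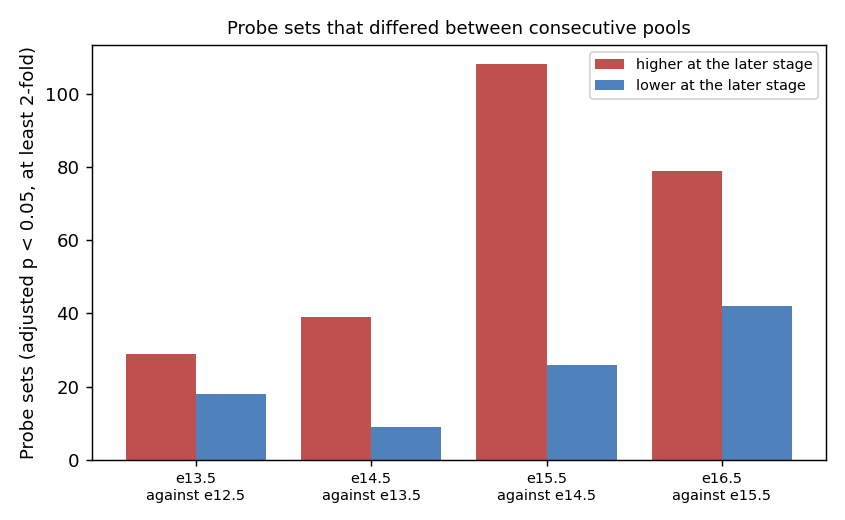
Number of probe sets (y axis) higher or lower by at least 2-fold between consecutive pools (x axis) at an adjusted p under 0.05. The bars for e14.5 to e15.5 stand for 108 higher and 26 lower, and those for e15.5 to e16.5 for 79 and 42.

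The last comparison looked for transient expression, setting the mean of e13.5, e14.5 and e15.5 against the mean of e12.5 and e16.5. Its error again holds the spread between labelling reactions only, so a higher middle cannot be told apart from a difference between pools. Chgb was higher in the middle by 1.58 ± 0.04 (SE over labelling reactions, 10 arrays), going from 7.83 ± 0.10 at e12.5 to 9.79 ± 0.07 at e14.5 and 7.76 ± 0.03 at e16.5. Cym, which encodes chymosin, was higher by 1.29 ± 0.07. Neurog3 followed the same course at a smaller size (0.94 ± 0.06, short of 2-fold), from 6.49 ± 0.18 at e12.5 to 7.95 ± 0.09 at e14.5 and 7.07 ± 0.07 at e16.5. Nkx2-2 (0.91 ± 0.04), Neurod1 (0.53 ± 0.04), Pdx1 (0.52 ± 0.04), Pax6 (0.43 ± 0.07) and Pax4 (0.27 ± 0.04) also had higher middle means, below the 2-fold minimum, with Neurod1 and Pax6 below the chip median at each stage. Ctrb1 (1.44 ± 0.04) and Ins2 (1.12 ± 0.04), whose values were highest at e16.5, and Hbb-y (1.16 ± 0.04), lowest at e16.5, met the call without a peak in the middle. For Ctrb1 the value rests on stages at the top of the chip's range and can come from saturation. Rnase1 (-2.11 ± 0.06), Sycn (-2.05 ± 0.05), Zg16 (-1.95 ± 0.05), Klk1 (-1.81 ± 0.05) and Pdia2 (-1.78 ± 0.05), highest at e16.5, were lower in the middle. Each of these 5 lay below the median of its chip at e12.5 and e13.5, so these differences rest partly on levels not shown above background. In all, 12 probe sets were higher and 37 lower in the middle (adjusted p under 0.05 and at least 2-fold). The 2 other probe sets of Chgb were dim and did not show the rise.

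**Figure D4:**
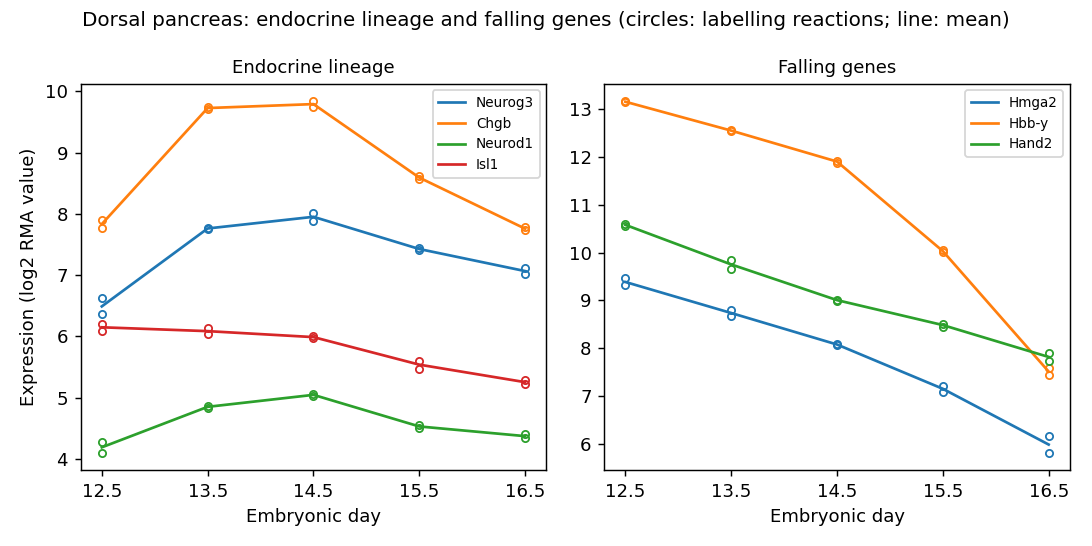
Log2 expression (y axis) of endocrine lineage genes and of falling genes by embryonic day (x axis), with a circle per labelling reaction and a line through the mean of the 2. Chgb and Neurog3 were highest at e14.5, and Hmga2 went from 9.38 to 5.98.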

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

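Cyclic loess was chosen after the data were seen, and the other alternatives before. Leaving out 1 labelling reaction on all chips gave 3328 to 4035 rising and 4439 to 4999 falling probe sets in the stage trend, 525 to 545 higher and 1090 to 1183 lower for e16.5 against e12.5, 47 to 56, 44 to 49, 134 to 141 and 121 to 144 in the consecutive comparisons, 11 to 16 higher and 32 to 37 lower in the middle, and 11 to 13 lists; a lone reaction is then assumed to vary like the others. Against 3886 rising and 4825 falling probe sets, 7957 and 7538 were called with 10 arrays as independent, and 5425 rising and 6208 falling with labelling reactions as a random block. Rising and falling probe sets were 2370 and 3797 when only bright ones were tested (fewer probe sets), and 525 and 981 with at least 2-fold as well. Counts fell with fewer pools, to 1874 and 3332 without e12.5, 2207 and 3301 without e13.5 and 1275 and 2278 without e16.5. With no fold minimum, e16.5 against e12.5 gave 9687 higher and 8594 lower, the 4 intervals 4122, 1160, 3922 and 7538, and the middle 3277 higher and 2297 lower. At 1.5-fold these were 1598 and 3303; 301, 196, 577 and 861; and 73 and 90. The lower fold limit by itself admits more probe sets. With an estimated correlation, 0 of 28 lists passed with camera in limma, against 12, and 1 had an unadjusted p under 0.05. The 12 called lists had estimates from 0.0201 (TGF-beta, BMP and hedgehog) to 0.672 (cell cycle), all above the preset of 0.01. Their p-values at the preset thus assume less correlation between genes than was estimated. The TGF-beta, BMP and hedgehog list, nearest to the preset, still went from a camera adjusted p of 0.00288 to 0.496. The size of the correlation was not the whole reason. In the simulation, with genes drawn independently, the shifted list went from a camera adjusted p of 1.62e-98 to 0.00427 with an estimated correlation. The Wnt list, with an estimate of -0.0182, below the preset, went from 0.0854 to 0.496. The losses thus do not show that correlation between genes undoes the list calls. What else caused them was not tested.

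Replicate numbers name labelling reactions. Over 30 pairs of stages, the differences between reactions 1 and 2 correlated by -0.176 to 0.110, with 1 pair over 0.1, so the numbers do not pair the samples. With the replicate number as a block the contrast counts were 527 and 1111 for e16.5 against e12.5 and 12 and 37 in the middle, 12 lists passed, and 7580 rising and 7313 falling probe sets were called in the trend, which then takes the 10 arrays as independent. Past the threshold, the direction reversed for Neurog3 without the e12.5 pool (-1.04) and for the leukocyte list without the e16.5 pool (adjusted p = 0.0185, down). Other signs turned without passing. Neurod1 was -0.0376 with quantile normalization again, -0.0283 with cyclic loess, -0.78 without the e12.5 pool and -0.0517 to 0.0877 with 1 labelling reaction left out. Pax4 was -0.41 without the e12.5 pool and -0.0377 to 0.0767 with 1 reaction left out. Pax6 was 0.31 without the e16.5 pool, 0.0138 without the e13.5 pool and -0.208 to 0.0173 with 1 reaction left out. Without the e16.5 pool Pdx1 was 0.68, Nkx2-2 0.029 and Col1a1 0.14. The red cell list turned down without the e16.5 pool (adjusted p = 0.874), the liver list turned down with bright probe sets only (0.756) and without the e12.5 pool (0.936), and the ribosomal list turned up with the mean of all probe sets of a gene (0.437) and with cyclic loess (0.1001); the cause of these was not tested. Of 3086 comparisons of a named gene's slope with an alternative, 88 lost the call, 12 gained it and 14 changed sign. Of 833 for contrasts 4 lost it, and of 644 for lists 22 lost it, 16 gained it and 6 changed sign. The contrast genes were picked as the largest calls. Some alternatives, such as the replicate block or leaving out an array of a stage outside the contrast, leave their folds unchanged. Few losses there were thus likely beforehand. Without detection calls, what the dimmest probe sets can show stays unknown.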

Other observations

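The added gene groups, granulocyte and spleen genes included, were chosen after the leading genes had been seen and leave out the genes that prompted them, and the tests of labelling noise, granulocytes, spleen tissue and blood were also chosen only after their result was seen. Genes of amino acid and one-carbon metabolism had 10 rises and 1 fall of 29, led by the asparagine synthetase gene Asns (2.88 ± 0.35), the transaminase gene Bcat2 (1.81 ± 0.33) and the amino acid transporter genes Slc7a5 (1.36 ± 0.13) and Slc7a1 (1.12 ± 0.15); the list had an adjusted p of 0.0123, and an adjusted p = 0.544 with an estimated correlation. Of 18 Hox genes 6 fell and none rose (adjusted p = 0.0552), among them Hoxa5 (-1.72 ± 0.15), Hoxa3 (-1.22 ± 0.15) and Hoxb2 (-1.16 ± 0.14). Of 11 oncofetal genes, a group prompted by the fall of Hmga2, 4 fell and none rose (adjusted p = 0.0552), with Cbx2 at -1.44 ± 0.10 and Gpc3 at -1.18 ± 0.13. Cholesterol synthesis genes had 5 rises and 1 fall of 19 (adjusted p = 0.204), and tRNA synthetase genes 2 rises of 19 (adjusted p = 0.0767), those of Lars (1.17 ± 0.17) and Nars (1.02 ± 0.13).

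Xist stood at 7.35 ± 0.14 in the e12.5 pool and between 5.61 and 6.06 in the later ones (log2 mean and SD of 2 labelling reactions), and a dimmer second probe set differed the same way, by 0.29. Noise between labelling reactions is argued against by the call from e12.5 to e13.5 (limma adjusted p = 4.29e-07), whose error is that noise. The reactions of e12.5 differed by 0.121 of the gap. Xist was picked by that call, so a small ratio was likely beforehand and adds no support of its own. More female embryos in the e12.5 pool may be the reason, and would lower Y-linked genes there. Eif2s3y was -0.63 from the later mean, Kdm5d -0.16 and Uty -0.06, with a median of -0.159, between the bounds set for and against. Eif2s3y and Uty were dim. The later mean holds the e16.5 pool, where Xist rose from 5.61 at e15.5 to 6.06, though not on its dimmer probe set (2.83 and 2.82). Over that interval Kdm5d, the bright Y-linked gene, changed by -0.49, and the median of the 3 genes was -0.12. These values were looked at afterwards, and the sex mix of the pools stays open. Stage itself, which the design does not separate from pool, was untested.

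S100a8, S100a9, Stfa3 and Olfm4, genes of neutrophils picked after their values were seen, were higher at e16.5 than at e15.5 by 2.84 ± 0.06, 2.78 ± 0.09, 2.11 ± 0.11 and 1.68 ± 0.11, with no slope past the threshold (adjusted p from 0.16). More blood of every kind in that pool is argued against as the whole reason, since Hba-a1, Hbb-b2 and Alas2 had a median difference of 0.116. Hba-a1, which gave that median, stood at 12.69 and 12.81, where signal can saturate. Hbb-b2 changed by -0.09 ± 0.07. Alas2, which was less bright, rose by 0.29 ± 0.06 (limma adjusted p = 0.00504), so some more blood is not excluded. More granulocytes in the e16.5 pool may add to it: 21 other granulocyte genes had a median difference of 0.34, and the 12 bright ones of 0.49, both short of the bound of 0.5, which was set after related values had been seen. Anxa1 (1.22 ± 0.10), Lyz2 (1.19 ± 0.09), Ngp (1.08 ± 0.07), Ltf (0.93 ± 0.09), Camp (0.84 ± 0.08) and Pglyrp1 (0.56 ± 0.09) were above it. The other 15 were not, among them the bright Hp (0.42 ± 0.06), Csf3r (0.35 ± 0.06), Lcn2 (0.34 ± 0.09), Elane (0.15 ± 0.06), Prtn3 (-0.08 ± 0.08) and Stfa1 (-0.13 ± 0.07). Of these 21 genes, 9 were dim, and Mpo and Lyz2 were also in the leukocyte list. Spleen tissue dissected with the e16.5 pancreata stays open too, with a median of 0.163 over 14 spleen and B cell genes, of which 7 were dim.

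Values on chip B spread more widely at e12.5, with an SD over probe sets of 1.64 and 1.62, than at e13.5 to e15.5, with 1.55 to 1.57, or at e16.5, with 1.51; chip A also narrowed at e16.5, to 1.91, from 1.94 to 1.97. From e12.5 to e13.5, brightness and the log2 difference had a Spearman correlation across probe sets, which are not independent, of -0.167 on chip B, 0.0711 on chip A and 0.0559 on chip C, and from e15.5 to e16.5 of -0.319, -0.269 and -0.167. A step on chip B that depends on brightness and not on the gene could add calls: over 882 genes with bright probe sets on chips A and B, the e13.5 minus e12.5 difference on chip B was lower by a median of -0.0419 (95% bootstrap interval -0.0687 to -0.0247), short of the 0.1 set in advance for such a step, with an interval past the 0.05 set against it, so a small step stays open, while chip B was higher by 0.0206, 0.0444 and 0.0187 in the next intervals and by 0.0354 (0.00538 to 0.0779) for e16.5 against e12.5. Against 132 higher and 589 lower calls on chip B for e16.5 against e12.5, cyclic loess, which removes differences that follow brightness, gave 135 and 577, median centring 125 and 634 and quantile normalization again 160 and 478. Loess moved chip A from 336 and 398 to 390 and 300, so such trends can move calls. On chip B these counts stayed near those without loess. A trend with brightness is thus argued against as the whole source of these 2-fold calls. The drop to 478 lower calls with quantile normalization again leaves scaling open as a part of them. In the stage trend, which has no fold minimum, 32.7% of probe sets passed on chip B, 23.1% on chip A and 15.0% on chip C. Loess moved the trend calls of chip B from 1977 rising and 2080 falling to 1597 and 2242. A trend with brightness thus stays open as a part of the trend calls there.

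Of the 60 orders of the 5 pools, an order and its reverse being 1, only the real order gave as many called probe sets as it did. So 1 of 60 splits of the pools by order reached 8711, the lowest share that 5 pools can give, and chance order can be excluded at 5% for the calls as a set. This does not bear on single probe sets, and it does not separate stage from pool or from anything else that ran in the same order. The highest other order gave 2060, with e12.5 and e13.5 exchanged.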
